A study of Mus musculus with 16 samples.

How the data were processed

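Poly(A)-selected RNA from the livers of male mice was sequenced as read pairs on an Illumina instrument, per the labels, in 16 libraries of 4 groups, WT and CryDKO mice given oxaliplatin at 12 mg/kg on 3 days at CT8 or CT16. The series text speaks both of a single dose and of dosing on 3 days, and gives no time of liver collection. According to the processing notes of the authors, reads were checked with FastQC, trimmed with Trimmomatic 0.35, aligned with STAR 2.5.3 to the mouse build GRCm39 (mm39) and counted with HTSeq 1.99.2, and DESeq2 was used after that. Their gene annotation, strand setting and parameters were not given in the sources used here.

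The deposited count table holds counts, whole numbers of reads for 40840 gene symbols in 16 columns that are not normalized. The second deposited table holds a normalized signal: from the values, each column is a count column divided by 1 size factor, and only the 19592 genes with at least 10 reads in total are listed. There, 4 CryDKO_CT8 columns carry each other's numbers, within the same group, so groups were not affected. Groups were taken from the column names. Columns carry a running number over the series, not a replicate number, so no libraries were paired. Library totals ranged from 18083916 to 29934138 reads, and the spread between libraries beyond counting error was estimated by the model.

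Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups, which left 14484, libraries were scaled by the trimmed mean of M values (TMM), and a quasi-likelihood model with the robust option was fitted to all 16 libraries with 1 coefficient per group. There were 5 comparisons: CT16 against CT8 in WT, the same in CryDKO, CryDKO against WT at CT8, the same at CT16, and the interaction of genotype and time. P values are two-sided, adjusted by Benjamini-Hochberg over the genes tested in a comparison, with a threshold of 0.05. Errors of log2 changes are approximate standard errors, each the size of the log2 change divided by the square root of the F statistic of that test. Errors of CPM are SD over 4 libraries.

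Gene lists, 33 in number, covered the clock, DNA damage and repair, platinum transport, detoxification, sex-biased expression, metabolism, stress and immune responses, liver zones, and markers of other cell types. Camera of limma 3.58.1 was run on voom values with a preset correlation of 0.01 for the 28 lists with at least 3 tested members, adjusted over lists within a comparison. The markers of B cells (2 tested members), T and NK cells (1), erythroid cells (2) and pancreas or fat (1) were too few to test, and none of 13 mitochondrially encoded mRNAs is in the count table, 0 found. Each list was also counted gene by gene, over all genes and adjusted over the list alone.

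Named genes followed a rule. Cry1 and Cry2 came first, in every library. Then came the 10 largest rises and 10 largest falls in each comparison, 5 and 5 for the interaction, among genes past the threshold with a mean log2 CPM of at least 1 and no overlap between the values of the groups, leaving out symbols that are only model or clone names. Where none passed, the 5 lowest p values were named as not passing. Up to 4 members of each list with the lowest adjusted p followed. Not every gene that meets the rule is given in the text. Those left out include genes that lost their calls in several alternatives, such as Acaa2, C1qa, Pdgfrb and Rgn by genotype at CT8. At CT16 they include Hmox1, Krt19, Col1a2 and Nudt7. Comparisons, gene lists, this rule and all but 2 kinds of alternative setting were chosen before the data were examined.

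The procedure was tested on simulated data made from the counts with known changes set in. In the comparison of times in WT it called 14% of genes changed 1.5-fold, 60% of 2-fold, 85.7% of 4-fold and 100% of 8-fold changes, and called 11 of 13957 unchanged genes. It also called 8 of 13957 unchanged genes by genotype at CT16 and 4 of 13957 for the interaction. By genotype at CT8 and for the times in CryDKO it called 0 of 14155. Alternatives were the DESeq2 1.42.0 Wald test, limma voom with and without quality weights, limma trend on log2 of the deposited normalized values with 1 added, size factors of DESeq2 in edgeR, scaling by library size alone, no low count filter, a mean of at least 50 reads, no robust option, a 2-fold threshold, only the groups of a comparison, and each library left out in turn. For lists they were camera with an estimated correlation or after scaling by size factors of DESeq2, and the directional and mixed tests of limma's fry. Correction for GC content of transcripts, from the GRCm38 reference annotation matched by symbol, and list tests without WT_CT16 library 8 were added after the data had been seen. Figures were drawn and flags computed with Python 3.11.15. No reads were realigned, and splicing, variants and the deleted part of either gene were not analysed here.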

Results

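Liver transcripts were measured by poly(A)-selected RNA sequencing in male mice that had received oxaliplatin, a platinum drug that crosslinks DNA, at 12 mg/kg by intraperitoneal injection on 3 consecutive days. The drug was given at circadian time 8 (CT8) or 16 (CT16), in mice kept in constant darkness, to wild-type (WT) animals and to animals lacking both cryptochromes, Cry1 and Cry2, the main repressors of the circadian clock (CryDKO). The labels give the strain C57BL/6J for both genotypes. The 16 libraries fell into 4 groups of 4. Counted reads per library ranged from 21083769 to 26512390 in WT at CT8 and from 23866799 to 29934138 in WT at CT16. They ranged from 21210401 to 23618273 in libraries labelled CryDKO at CT8 and from 18083916 to 24967995 in those at CT16. No untreated group was analysed here, and the time between injection and liver collection was not given in the sources used here. The labels do not say that the replicates of a group came from separate animals, so every p measured the spread between these samples, which may be partly technical. No 2 libraries of a group agreed within sampling noise (chi-square per degree of freedom of 25.1 to 169.5). Libraries are named by their group and by the running number that their columns carry, which is not a replicate number.

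**Figure D1:**
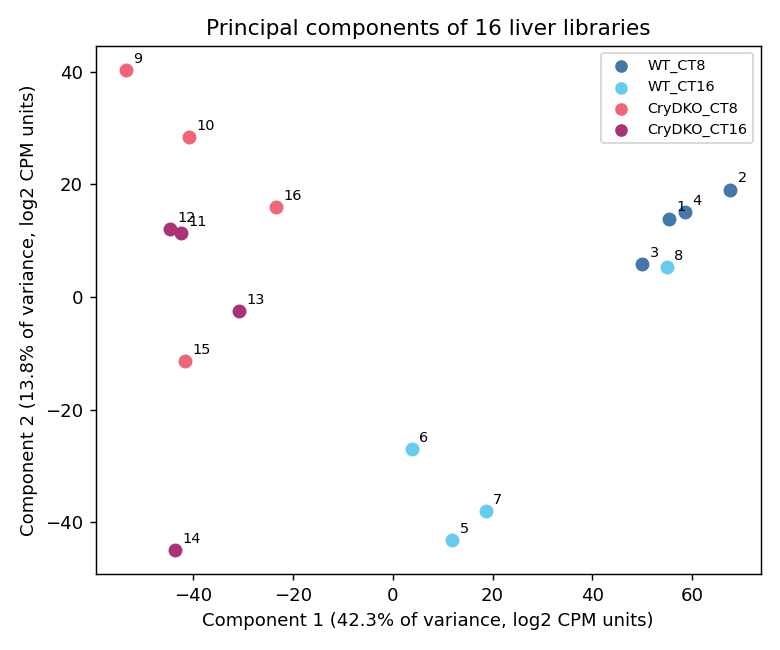
Principal components 1 (42.3% of the variance) and 2 (13.8%) of log2 CPM, with each point a library, its colour the group and its number the column number. Component 1 set the libraries labelled CryDKO apart from the WT libraries, and WT_CT16 library 8, at 54.9, lay among the WT_CT8 libraries, at 50.03 to 67.7.

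The targeted genes were examined first. Cry2 was lower in all 8 libraries labelled CryDKO, at 23.1 to 33.3 CPM, the read count scaled to a common library size, than in the 8 WT libraries, at 39.9 to 58.9 CPM. Cry1 went the other way, with 20.5 to 29.0 CPM in the libraries labelled CryDKO and 5.14 to 15.9 CPM in WT. Reads summed over a whole gene do not show which part of it was deleted, and the labels do not name that part, so these counts did not check the knockout itself. Arntl, which encodes the clock activator BMAL1, lay at 0.941 to 3.53 CPM in WT and at 5.48 to 14.3 CPM in the libraries labelled CryDKO. Because the Cry1 counts went against a plain loss of transcript, CryDKO stands for the label alone, and each direction by genotype rests on the labels.

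**Figure D2:**
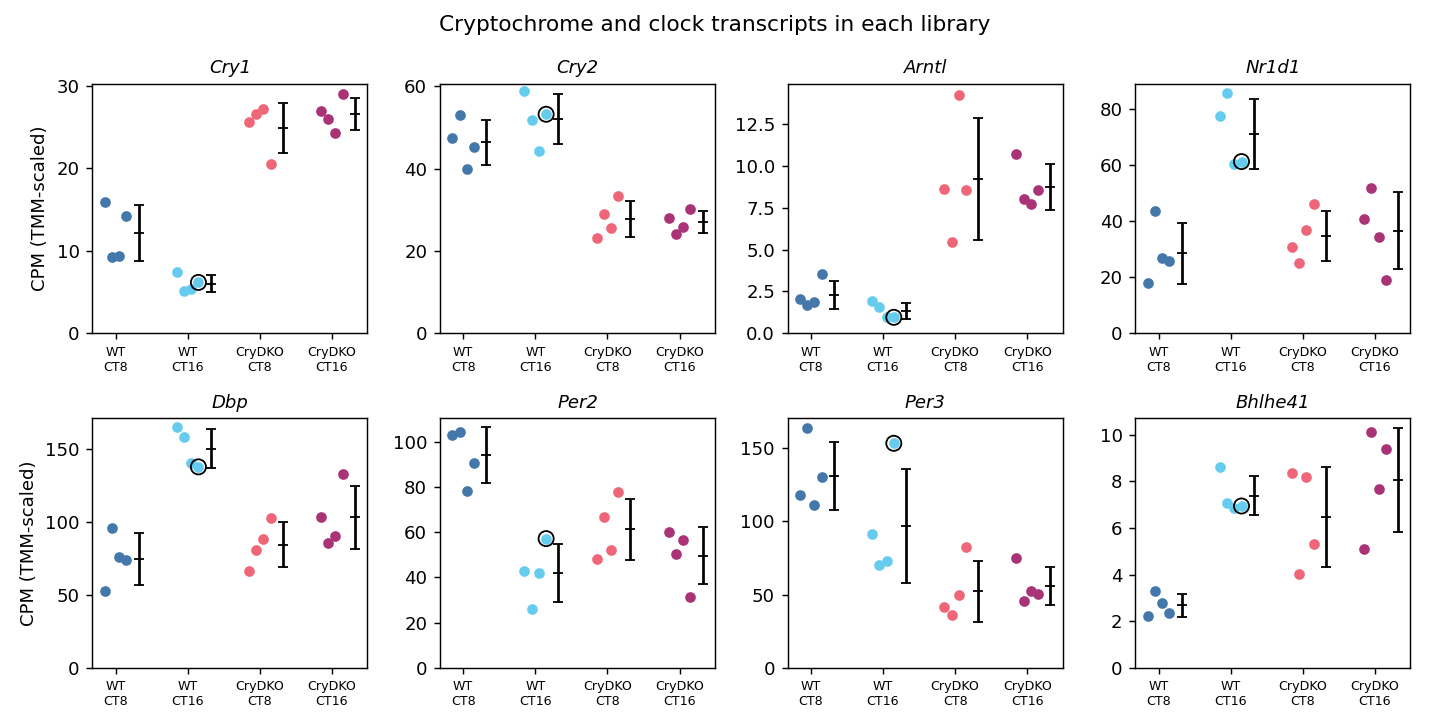
TMM-scaled CPM of Cry1, Cry2 and 6 clock genes in each library (points), with the mean and SD of each group of 4 at its right and WT_CT16 library 8 circled. In WT, Nr1d1, Dbp and Bhlhe41 were higher and Cry1 and Per2 lower at CT16 than at CT8, while the groups labelled CryDKO overlapped in these 5 genes.

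The first comparison asked how WT livers differed between dosing at CT16 and at CT8. Because the time of liver collection was not given, dosing time and circadian phase at collection cannot be told apart. Several clock genes differed. Nr1d1, which encodes the repressor REV-ERB alpha, rose from 28.4 ± 10.9 CPM at CT8 to 71.2 ± 12.5 CPM at CT16 (SD, n = 4), a log2 change of 1.32 ± 0.29 (SE). Dbp, an activator of D-box genes, rose from 74.7 ± 17.8 to 150.5 ± 13.4 CPM, and Bhlhe41, a repressor of E-box genes, from 2.67 ± 0.483 to 7.37 ± 0.837 CPM. Per2 fell from 94.2 ± 12.2 to 41.99 ± 12.7 CPM and Cry1 from 12.2 ± 3.37 to 6.00 ± 1.02 CPM. In each of these genes the 4 values at CT8 and the 4 at CT16 did not overlap, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.0245 for Per2, 0.0390 for Nr1d1 and 0.0201 for Dbp, Bhlhe41 and Cry1. Of the 14 tested clock genes driven by E-box or D-box elements 3 rose, 2 fell and 9 did not pass, both over all genes and adjusted over the list alone.

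Outside the clock, among the largest rises were those of the magnesium transporter gene Nipal1 (log2 change 1.84 ± 0.43), Cables1 (1.45 ± 0.39), the cyclophilin gene Ppib (1.32 ± 0.19), and the fructose transporter gene Slc2a5 (1.31 ± 0.26). Next came the cathepsin gene Ctsl (1.23 ± 0.29), Srp54a (1.22 ± 0.30) and the sialyltransferase gene St6gal1 (1.20 ± 0.23). The largest falls were those of Lingo4 (-2.27 ± 0.54), Fbf1 (-2.17 ± 0.44), Tnnc1 (-1.69 ± 0.33), Tcim (-1.69 ± 0.32) and the long noncoding RNA Meg3 (-1.64 ± 0.36). Next came Pnldc1 (-1.52 ± 0.35), Ttll8 (-1.50 ± 0.39), Cabyr (-1.46 ± 0.32), the histidine decarboxylase gene Hdc (-1.45 ± 0.24) and Pisd-ps1 (-1.34 ± 0.26). Pisd-ps1 and Srp54a have near-identical copies, so their counts are uncertain. Mlxipl, which encodes the carbohydrate response factor ChREBP, fell by 1.19 on the log2 scale. Among DNA repair genes Ddb1 (0.62 ± 0.16) and Rpa1 (0.49 ± 0.13) rose and Ddb2 (-1.08 ± 0.27) and Slx4 (-1.02 ± 0.25) fell, while 0 of 25 p53 targets and 0 of 16 platinum transporters passed the same test. Every gene named here separated its 4 values at CT8 from its 4 at CT16 except Ddb1 and Rpa1.

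In all, 367 of 14484 genes differed between the times in WT, 179 higher and 188 lower at CT16, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p under 0.05. With scaling by library size alone, 18 of 372 genes were higher and 354 lower. The number turned on single libraries: it was 80 without WT_CT8 library 1, 5 without library 2, 92 without library 3 and 0 without library 4. It was 0 without WT_CT16 library 5, 1 without library 6, 12 without library 7 and 3580 without library 8. Leaving out CryDKO_CT8 library 9 gave 633, CryDKO_CT16 library 13 gave 174 and library 14 gave 697. All 367 genes remained among the 3580, and each gene named for this comparison lost its call in at least 1 of these fits.

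Several lists of hepatocyte functions stood higher at CT16 in WT by camera with a preset correlation, although few of their members passed alone. In the acute phase response, Crp (0.81 ± 0.21) and Lbp (1.01 ± 0.26) rose and 23 of 25 did not pass. Adjusted over the list alone 16 rose and 0 fell. The camera test gave adjusted p = 5.82e-08, and adjusted p = 0.869 with an estimated correlation. Gpt (0.77 ± 0.20) and Cps1 (1.00 ± 0.27), which handle amino acid nitrogen, rose among 20 genes of gluconeogenesis and amino acid catabolism. Adjusted over the list alone 11 rose and 1 fell. By camera the list had adjusted p = 1e-04, and adjusted p = 0.869 with an estimated correlation. Of 11 periportal hepatocyte genes 1, Cps1, rose (6 and 0 adjusted over the list alone). Camera gave adjusted p = 0.00011, and adjusted p = 0.869 with an estimated correlation. Of 23 genes of the unfolded protein and integrated stress response 1, Pdia6 (0.82 ± 0.19), rose (7 and 0 adjusted over the list alone). The camera test gave adjusted p = 0.000261, and adjusted p = 0.869 with an estimated correlation. The female-biased liver genes were called higher with 0 of 14 members past the threshold (camera adjusted p = 0.0464, adjusted p = 0.869 with an estimated correlation), and without WT_CT16 library 8 that call ended at adjusted p = 0.176. Without library 8, 12 gluconeogenesis, 13 acute phase, 9 unfolded protein response and 9 periportal genes rose. The macrophage and sinusoidal endothelium markers were then called lower by camera, with adjusted p = 0.00537 and 0.0168, and no estimated correlation was run for these calls. With the trend on GC content removed, the female-biased call ended (camera adjusted p = 0.0597) and the endothelium markers were called (0.0492). With scaling by library size alone 0 members of the acute phase, gluconeogenesis, periportal and unfolded protein lists passed edgeR's quasi-likelihood test, although the median of each list stayed above 0. In the interferon response Oasl1 (0.59 ± 0.15) and Ifih1 (0.49 ± 0.13) rose among 31 genes.

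The second comparison put the same question to the libraries labelled CryDKO. No gene differed between CT16 and CT8 by edgeR's quasi-likelihood test, where 938 genes had an unadjusted p under 0.05, while DESeq2 called 13, limma voom 0 and limma on the deposited normalized values 1. The lowest p values belonged to Sult5a1, a sulfotransferase gene, with 0.501 ± 0.113 CPM at CT8 and 2.52 ± 0.483 at CT16. Next came Isyna1, which makes inositol phosphate, with 15.7 ± 1.70 and 38.5 ± 16.7, and Tnfaip3, a brake on NF-kB signalling, with 6.72 ± 2.74 and 2.504 ± 0.484. Fmn2 (0.360 ± 0.263 and 1.72 ± 0.747 CPM) and the water channel gene Aqp4 (2.24 ± 1.92 and 0.346 ± 0.363 CPM) followed. The smallest of these, for Sult5a1, was adjusted p = 0.0828 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Nr1d1 stood at 34.6 ± 9.003 CPM at CT8 and 36.5 ± 13.8 at CT16, Dbp at 84.5 ± 15.3 and 103 ± 21.4, and Per2 at 61.3 ± 13.6 and 49.7 ± 12.8. Leaving out CryDKO_CT16 library 11 gave 3 genes, and leaving out WT_CT8 library 1 or WT_CT16 library 6 gave 1 each.

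With 0 members past the threshold in any list, camera still called 13 lists in the libraries labelled CryDKO. Higher at CT16 were the pericentral hepatocyte genes (adjusted p = 4.13e-06, and adjusted p = 0.517 with an estimated correlation), of which 2 passed adjusted over the list alone. The same held for xenobiotic phase I genes (0.000981 and adjusted p = 0.467 with an estimated correlation), cholesterol synthesis (0.00178 and adjusted p = 0.755 with an estimated correlation), male-biased genes (0.00343 and 0.755), bile acid genes (0.0140 and 0.617) and macrophage markers (0.0147 and 0.755). Lower at CT16 were the stellate cell and fibroblast markers (adjusted p = 1.22e-06, and adjusted p = 0.517 with an estimated correlation). Also lower were heat shock genes (0.00562 and adjusted p = 0.745 with an estimated correlation), endothelium markers (0.00639 and 0.749), neutrophil markers (0.0140 and 0.617), cholangiocyte markers (0.0140 and 0.617), NRF2 targets (0.0143 and 0.617) and periportal genes (0.0281 and 0.755). None of these calls held with an estimated correlation.

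The third comparison asked how the livers differed by genotype when the drug was given at CT8. Among the genes with the largest changes were some that mouse liver normally transcribes more in females, higher in the libraries labelled CryDKO, and genes of major urinary proteins (Mup), lower in them. Cyp2b9, a female-biased cytochrome P450, rose from 1.29 ± 0.618 to 234 ± 112 CPM (log2 change 7.50 ± 0.73). Nudt7, a male-biased peroxisomal hydrolase gene, fell from 239.8 ± 41.2 to 51.5 ± 9.66 CPM (-2.22 ± 0.32). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 2.65e-05 for Cyp2b9 and 0.000115 for Nudt7, and all 4 libraries labelled CryDKO lay beyond all 4 WT libraries in each.

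Cyp2b13, a close paralog of Cyp2b9, had 0 reads in WT at CT8 and 78.5 ± 93.0 CPM in the libraries labelled CryDKO, at least 2942-fold higher over a floor of 3 reads in the WT group. The reads came mostly from libraries 9 and 16, at 129.9 and 184 CPM, while libraries 10 and 15 had 0.270 and 0.166 CPM. Its call was lost in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment without WT_CT8 library 1 (adjusted p = 0.0678), 2 (0.0762), 3 (0.0660) or 4 (0.0711), without WT_CT16 library 5 (0.0529), 6 (0.0532), 7 (0.0538) or 8 (0.0946), and without the library labelled CryDKO of number 9 (0.0683), 16 (0.0672) or 11 (0.0530). Other large rises were those of Tdg-ps2 (7.42), Nat8f7 (6.81), Cyp2b10 (6.04), Smpdl3b (5.80), Lrtm2 (5.75), the leptin receptor gene Lepr (5.28) and Tmprss4 (5.26) on the log2 scale. Smpdl3b went from 0.338 ± 0.114 to 18.7 ± 6.401 CPM and Lepr from 1.18 ± 0.457 to 46.6 ± 33.4 CPM. Among the deepest falls were those of Mup-ps16 (-7.63), Mup17 (-7.09), Mup-ps12 (-5.46), Mup15 (-5.12), Mup12 (-4.95), Mup16 (-4.55) and Mup11 (-4.05). Also deep were those of the noncoding RNA Snhg11 (-4.56), Raet1d (-4.21), a ligand of the NKG2D receptor, and the steroid dehydrogenase gene Hsd3b5 (-4.61). Reads of the Mup genes, of Cyp2b9 and Cyp2b13, and of Tdg-ps2 can fall on near-identical copies, and overlapping or antisense genes cannot be told apart because the strand setting was not given, so the value of each such gene alone is uncertain. The sum over 25 Mup genes lay at 718 to 4679 CPM in the libraries labelled CryDKO at CT8 and at 10601 to 14546 CPM in WT at CT8. Reads of 4 Y-linked genes lay in the libraries labelled CryDKO at 51.4% to 87.0% of the WT mean. Hsd3b5 lost its call without WT_CT8 library 2 (adjusted p = 0.0529) or 4 (0.0563) and without CryDKO_CT8 library 9 (0.0724), 10 (0.0665) or 16 (0.0651) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

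**Figure D3:**
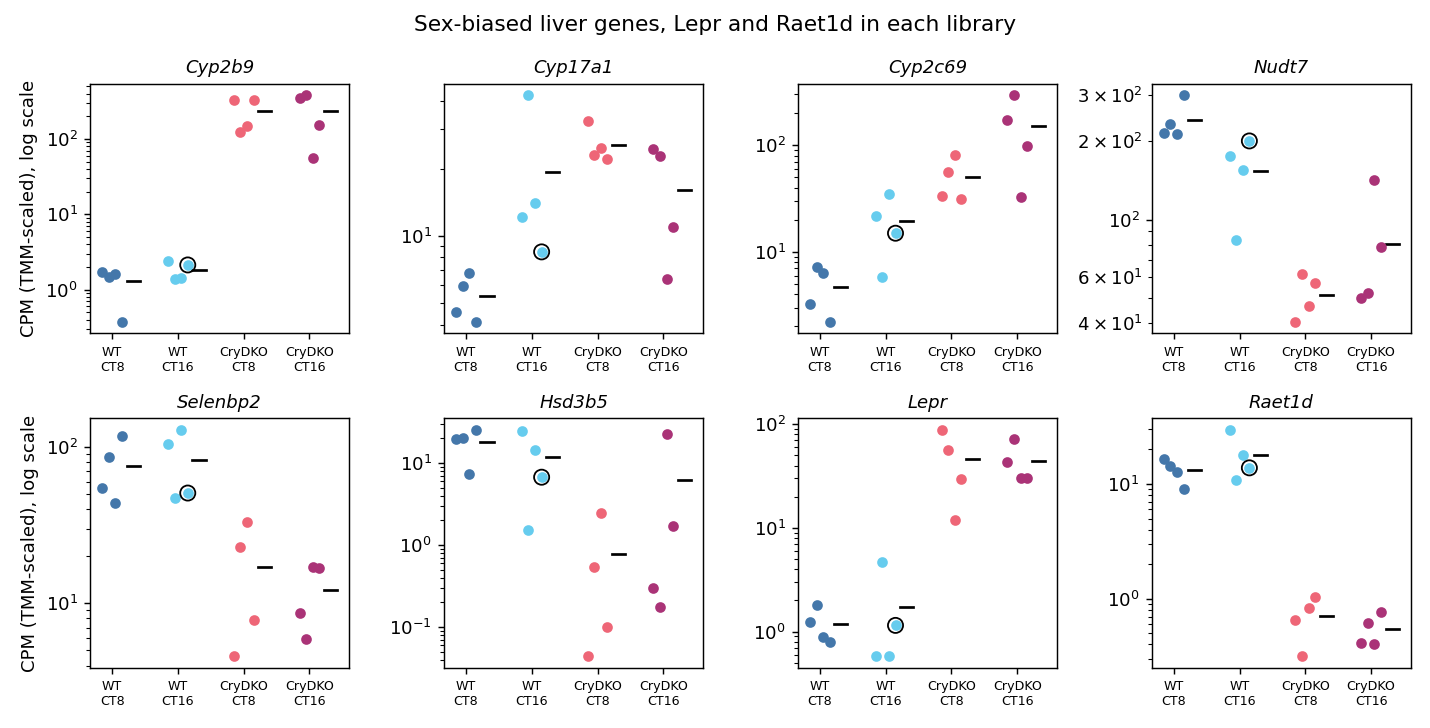
TMM-scaled CPM on a log axis of 3 female-biased (Cyp2b9, Cyp17a1, Cyp2c69) and 3 male-biased liver genes (Nudt7, Selenbp2, Hsd3b5), Lepr and Raet1d in each library (points), with the group mean as a bar and WT_CT16 library 8 circled. Cyp2b9 lay at 0.375 to 2.39 CPM in the WT libraries and at 55.4 to 384 CPM in the libraries labelled CryDKO.

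Among clock genes at CT8, Arntl rose (2.01 ± 0.30), as 1 of 3 tested genes repressed by REV-ERB. Of the 14 genes driven by E-box or D-box elements, Bhlhe41 (1.27 ± 0.25) and 3 others rose while Per3 (-1.32 ± 0.27) and 3 others fell. Among genes of nitrogen and glucose metabolism, the urea cycle enzyme gene Cps1 stood at 1891 ± 74.7 CPM in WT and 3725 ± 1094 in the libraries labelled CryDKO. There were also rises of the pyruvate carboxylase gene Pcx (1.01 ± 0.20), the transaminase gene Gpt (0.97 ± 0.20) and Igfbp1 (3.15 ± 0.70). In gluconeogenesis and amino acid catabolism 10 of 20 members rose and 0 fell, as did 10 adjusted over the list alone. By camera the list had adjusted p = 0.00122, and adjusted p = 0.797 with an estimated correlation. Of 11 periportal genes 8 rose, 9 adjusted over the list alone, including Cdh1 (1.79 ± 0.34), Hsd17b13 (1.03 ± 0.22) and the glutaminase gene Gls2 (1.12 ± 0.32). Camera gave adjusted p = 0.00122, and adjusted p = 0.797 with an estimated correlation. Of 23 genes of the unfolded protein response 11 rose and 0 fell, 12 and 0 adjusted over the list alone. Among them were the chaperone genes Hyou1 (1.26 ± 0.21), Hspa5 (0.87 ± 0.19), Creld2 (1.12 ± 0.23) and Pdia6 (0.85 ± 0.19). The camera test gave adjusted p = 0.000877, and adjusted p = 0.797 with an estimated correlation.

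Acute phase and interferon genes differed in direction at CT8. In the acute phase response 14 of 25 genes rose and 1 fell, also adjusted over the list alone. Examples were Cd14 (3.14 ± 0.41), Serpina3m (1.13 ± 0.22) and the heme scavenger gene Hpx (1.25 ± 0.25), which rose, and Saa3 (-0.98 ± 0.18), which fell. By camera the list had adjusted p = 0.00195, and adjusted p = 0.797 with an estimated correlation. In the interferon response 0 rose and 11 of 31 fell, also adjusted over the list alone, among them Irf7 (-0.87 ± 0.17), Xaf1 (-1.63 ± 0.37) and Stat2 (-0.90 ± 0.22). Camera gave adjusted p = 0.0204, and adjusted p = 0.812 with an estimated correlation. Male-biased genes fell in 5 of 18 cases and rose in 0, also adjusted over the list alone. Female-biased genes, with Cyp2c69 (3.41 ± 0.73) and the steroid hydroxylase gene Cyp17a1 (2.26 ± 0.51), rose in 7 of 14 and fell in 1, 9 and 1 adjusted over the list alone. Camera gave adjusted p = 0.00122 for the male-biased and 0.00292 for the female-biased list, and adjusted p = 0.797 with an estimated correlation for each. Of 13 stellate cell and fibroblast markers 4 rose, including the collagen genes Col1a1 (1.62 ± 0.35) and Col1a2 (1.42 ± 0.24), 4 adjusted over the list alone. The camera test gave adjusted p = 0.00901, and adjusted p = 0.797 with an estimated correlation. Other markers of cells outside hepatocytes passed in 2 of 12 macrophage genes (0 adjusted over the list alone), 2 of 6 cholangiocyte genes with Krt19 at 2.10 ± 0.43, 0 of 6 neutrophil genes and 0 of 11 endothelial genes.

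Of 15 NRF2 targets 8 rose at CT8 and 1 fell, 9 and 1 adjusted over the list alone. Among them were Pgd (1.02 ± 0.20) and Tkt (0.85 ± 0.19) of the pentose phosphate pathway and Hmox1 (1.46 ± 0.39) up and Aox1 (-1.06 ± 0.21) down. By camera the list had adjusted p = 0.0204, and adjusted p = 0.797 with an estimated correlation. Of 18 glutathione and metallothionein genes 7 rose and 1 fell, 8 and 1 adjusted over the list alone, with Gss (0.81 ± 0.18) and Gsr (0.66 ± 0.19) up and Mgst1 (-0.87 ± 0.19) down. Camera gave adjusted p = 0.0458, and adjusted p = 0.797 with an estimated correlation. That call ended without WT_CT16 library 8 (adjusted p = 0.0564) and after a trend with GC content was removed (0.0519).

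Lists on the DNA damage response were not called by camera at CT8, though single members moved. Of 25 p53 targets 6 rose, with the cell cycle inhibitor gene Cdkn1a (1.38 ± 0.38) and Btg2 (1.64 ± 0.44), and 3 fell, with Mdm2 (-0.79 ± 0.20) and Rps27l (-1.39 ± 0.26), also adjusted over the list alone. In nucleotide excision repair 11 of 31 rose, with Ddb1 (0.89 ± 0.16), and 4 fell, with Uvssa (-1.34 ± 0.19), 11 and 5 adjusted over the list alone. In crosslink and homologous recombination repair 2 of 15 rose, with Brca1 (0.95 ± 0.23), and 6 fell, with Brca2 (-1.20 ± 0.23), also adjusted over the list alone. Of 16 platinum transporters 2 rose, with Abcc4 (1.59 ± 0.41), and 1 fell, also adjusted over the list alone.

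The remaining lists were mixed at CT8. With no list called by camera, bile acid genes rose in 4 and fell in 4 of 15 cases, with Cyp7a1, the rate-limiting enzyme of the classical pathway, down (-1.85 ± 0.33) and Cyp8b1 up (1.12 ± 0.27). Xenobiotic phase I genes rose in 4 and fell in 4 of 19, with Cyp2a5 (-1.16 ± 0.24) and Cyp3a25 (-1.35 ± 0.20) down. Fatty acid synthesis rose in 5 and fell in 2 of 18, with Elovl5 (1.54 ± 0.40) up and Mlxipl (-1.21 ± 0.29) and Me1 (-0.82 ± 0.21) down. Adjusted over the list alone, 6 fatty acid genes rose and 2 fell, 2 cholesterol genes rose and 1 PPAR alpha target rose, and the other lists of this paragraph kept their counts. PPAR alpha targets rose in 5 of 23, with Pdk4 (1.46 ± 0.36), cholesterol synthesis in 3 of 25, and heat shock genes in 5 of 16. Proliferation genes rose in 3 and fell in 1 of 20, and pericentral genes rose in 2 and fell in 3 of 12. With scaling by library size alone the balance turned to falls in the p53 (2 and 6), excision repair (2 and 10), transporter (1 and 8), heat shock (0 and 3), cholesterol (1 and 4), PPAR alpha (1 and 2), fatty acid (1 and 2) and proliferation (1 and 3) lists. It also left more falls than rises among clock genes driven by E-box or D-box elements (1 and 5), bile acid (3 and 5), xenobiotic (1 and 8) and pericentral (1 and 7) genes.

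In all, 5649 of 14484 genes differed by genotype at CT8 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p under 0.05, with 2706 higher and 2943 lower in the libraries labelled CryDKO. Of these, 687 rose and 1592 fell by at least 2-fold. Scaling by library size alone moved the median gene from -0.02 to -0.36 on the log2 scale and gave 961 higher and 5127 lower, so directions here are relative to the TMM scaling. Fold changes rose with the GC content of the transcripts (Spearman rho 0.333 across genes, which are not independent replicates), and 4872 genes passed after that trend was removed from each library.

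The fourth comparison put the same question at CT16. Many of the same transcripts stood apart: Cyp2b9 at 1.84 ± 0.498 CPM in WT and 236 ± 159 in the libraries labelled CryDKO, Smpdl3b at 0.312 ± 0.111 and 23.2 ± 5.62, Lepr at 1.75 ± 1.97 and 43.8 ± 19.5, and Raet1d at 17.99 ± 8.30 and 0.550 ± 0.177. The serum amyloid gene Saa2, among the most abundant acute phase transcripts, fell from 6396 ± 1550.0 to 966 ± 516 CPM (log2 change -2.73 ± 0.65). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 5.90e-05 for Cyp2b9, 3.85e-10 for Smpdl3b, 0.00183 for Lepr, 1.28e-07 for Raet1d and 0.0115 for Saa2, each with no overlap between the 4 libraries of either genotype.

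On the log2 scale, further rises were those of Tdg-ps2 (8.21), Nup62cl (4.32), Cyfip2 (4.23), Lingo4 (3.48) and the recombination gene Rad51b (3.12). Nat8f7, with 1 read over the 4 WT libraries, stood at 10.2 ± 3.80 CPM in those labelled CryDKO. Further falls were those of Mup-ps16 (-4.85), Raet1e (-4.57), Clec2h (-3.66), Ddah1 (-3.33), which breaks down methylarginines, Snhg11 (-3.11), Selenbp2 (-2.77), the lipoprotein lipase gene Lpl (-2.56) and Tiam2 (-2.50). Lpl lost its call without CryDKO_CT16 library 12 (adjusted p = 0.0547, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

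Arntl rose again at CT16 (2.72 ± 0.31), with 2 of 3 genes repressed by REV-ERB up. Of the 14 genes driven by E-box or D-box elements 2 rose and 4 fell, 5 adjusted over the list alone, with Nr1d1 at 71.2 ± 12.5 CPM in WT and 36.5 ± 13.8 in the libraries labelled CryDKO. The Nr1d1 call was lost without WT_CT16 library 5 (adjusted p = 0.0676) or 6 (0.0744) and without CryDKO_CT16 library 11 (0.0509), 13 (0.0757) or 14 (0.0625) in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Macrophage and Kupffer cell markers rose in 5 of 12 cases and fell in 0, 6 and 0 adjusted over the list alone, with the complement genes C1qa (1.39 ± 0.30) and C1qb (1.45 ± 0.33), while 9 rose without WT_CT16 library 8 and 2 rose with scaling by library size alone or after the GC trend was removed. The camera test gave adjusted p = 3.43e-05, and adjusted p = 0.994 with an estimated correlation. Interferon response genes rose in 0 and fell in 8 of 31, 11 adjusted over the list alone, with the sensor gene Ifih1 (-0.81 ± 0.13), Ifit1 (-1.48 ± 0.26), Xaf1 (-1.66 ± 0.38) and Oasl1 (-0.61 ± 0.15). By camera the list had adjusted p = 0.000438, and adjusted p = 0.994 with an estimated correlation. Male-biased genes rose in 0 and fell in 3 of 18, also adjusted over the list alone (camera adjusted p = 0.00664, and adjusted p = 0.994 with an estimated correlation), with 1 left without WT_CT16 library 8 or after the GC trend was removed. The sum over 25 Mup genes reached 10305 CPM in CryDKO_CT16 library 13, above the lowest WT library at 7816 CPM, so the total of these transcripts did not separate the genotypes at CT16. Female-biased genes rose in 4 of 14, 7 adjusted over the list alone, with Cyp2c69 (2.96 ± 0.70), and 1, Cyp2g1, fell (-3.38 ± 0.52), and the list was not called (camera adjusted p = 0.119). It was called after the GC trend was removed (0.0374), as were the genes repressed by REV-ERB (0.00948). No estimated correlation was run after that correction, and without it both lists had adjusted p = 0.994 with an estimated correlation.

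No other list was called at CT16. In the acute phase response 4 of 25 rose, with Cd14 (2.56 ± 0.41), and 3 fell, with Saa3 (-1.52 ± 0.18) beside Saa2. Of 25 p53 targets 6 rose and 0 fell, with Bax (1.12 ± 0.20) and Ddit4l (2.04 ± 0.51). Without WT_CT16 library 8 that list was called with camera adjusted p = 0.0383, though only 3 members then passed, and it was also called after the GC trend was removed (0.0444). No estimated correlation was run for these calls, and with all libraries and no correction it gave adjusted p = 0.994. In nucleotide excision repair 4 of 31 rose, with Ercc3 (0.67 ± 0.14), and 2 fell, with Uvssa (-0.78 ± 0.19). In homologous recombination repair 2 of 15 rose and 3 fell, with the helicase gene Blm (-1.84 ± 0.40). Gluconeogenesis rose in 1 of 20, the unfolded protein response in 3 of 23, with Creld2 (1.51 ± 0.23) and Hyou1 (1.03 ± 0.21), and the periportal list in 0 of 11. NRF2 targets rose in 3 and fell in 2 of 15, with Tkt (0.87 ± 0.19) up and Ugdh (-0.87 ± 0.20) down. Glutathione genes rose in 2 and fell in 1 of 18, with Gstt1 (0.70 ± 0.16) up and Gstm2 (-0.98 ± 0.22) down. Xenobiotic genes rose in 2 and fell in 2 of 19, with Cyp2a5 (-1.89 ± 0.24) down. Platinum transporters rose in 1 of 16, and PPAR alpha targets in 2 of 23, with Pdk4 (1.67 ± 0.37). Fatty acid synthesis rose in 2 and fell in 1 of 18, with Acacb (1.17 ± 0.28) up. Cholesterol synthesis, bile acid and cholangiocyte lists each had 1 rise and 1 fall among 25, 15 and 6 genes. Heat shock, proliferation and endothelial lists each had 1 rise, that of the endothelium being Stab2 (1.11 ± 0.20). Pericentral and stellate lists had 2 each, with Rhbg (1.44 ± 0.31), while no neutrophil marker passed. Adjusted over the list alone, the rises and falls were 6 and 3 in excision repair, 4 and 2 among NRF2 targets, 3 and 2 among xenobiotic genes and 1 and 0 among stellate markers. They were 0 and 0 among transporters, gluconeogenesis, cholesterol and heat shock genes, and they were as over all genes in the other lists. With scaling by library size alone there were more falls than rises in excision repair (2 and 3), recombination repair (0 and 3), transporters (0 and 2), glutathione (1 and 2), xenobiotic (0 and 2), bile acid (1 and 2), cholesterol (0 and 1), periportal (0 and 1) and cholangiocyte (0 and 1) genes.

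**Figure D4:**
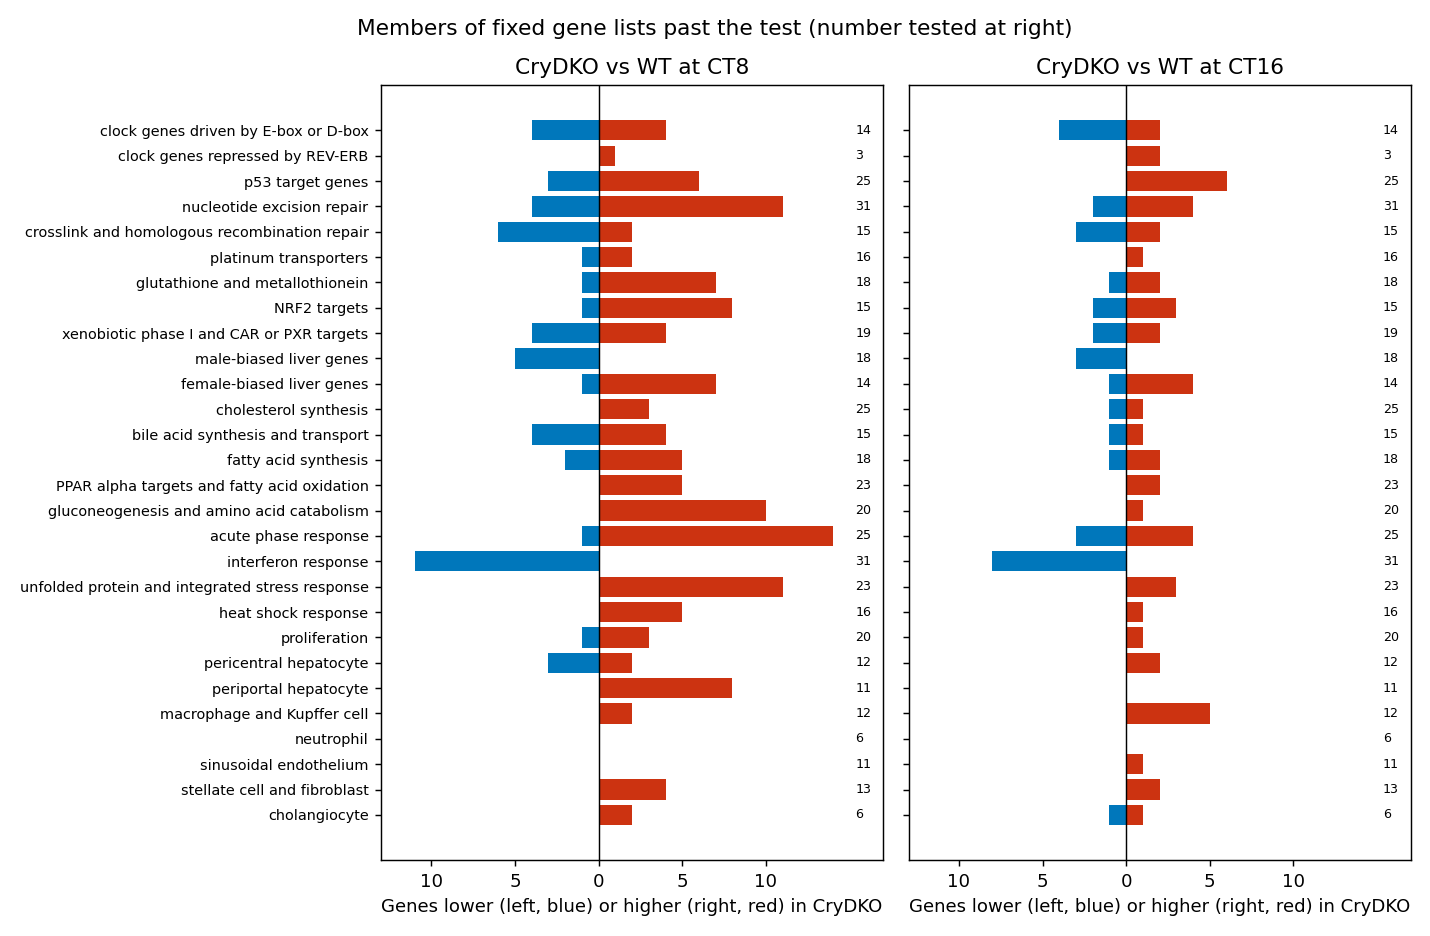
Number of members past the threshold in each fixed gene list, lower (left, blue) or higher (right, red) in libraries labelled CryDKO, with the number tested at the right of each panel. At CT8 the acute phase list had 14 higher and 1 lower and the interferon list 0 and 11, and with scaling by library size alone the p53, excision repair, transporter and heat shock lists had more falls than rises at CT8.

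In all, 2629 of 14484 genes differed by genotype at CT16 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p under 0.05, with 1303 higher and 1326 lower, and 350 rose and 540 fell by at least 2-fold. Scaling by library size alone gave 605 higher and 1883 lower, with the median gene at -0.16 on the log2 scale. Fold changes rose with GC content here too (Spearman rho 0.419 across genes), and 1493 genes passed after that trend was removed, 1264 of them among the 2629.

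Between the times, 892 genes were higher in the libraries labelled CryDKO at both CT8 and CT16, where independent lists of the same lengths would share 243, and 948 were lower at both, against 269. Opposite directions were found for 3 genes higher at CT8 and 2 genes lower at CT8. Over all tested genes the log2 changes at the 2 times correlated with Pearson r = 0.721 and Spearman rho = 0.697, with different WT libraries at each time. Fold changes rose with GC content at both times, and a GC bias or batch that follows genotype would act on both comparisons. The sharing of genes and the correlations therefore cannot tell an effect of genotype from such a bias or batch. Whether the effect of genotype itself depended on the time was tested as an interaction, which no fit of 2 groups can give. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 6 of 14484 genes passed, 4 with a positive and 2 with a negative term. The term was 2.98 ± 0.50 for Sult5a1, 2.05 ± 0.35 for the epoxygenase gene Cyp2j9, -2.09 ± 0.37 for Tnfaip3 and -1.72 ± 0.26 for Ppib. The others, 3.38 ± 0.59 for Gm43549 and 3.38 ± 0.60 for LOC118568335, lie outside the rule for named genes and were chosen after their values were seen. Ppib stood at 24.7 ± 6.404 and 61.8 ± 6.33 CPM in WT at CT8 and CT16, and at 57.2 ± 15.9 and 43.5 ± 3.60 CPM in the libraries labelled CryDKO. The number was 0 without library 2, 4, 5, 12 or 13, 1 without 9, 2 without 1 or 6, 3 without 10 and 568 without WT_CT16 library 8, so the larger count at CT8, 5649 against 2629, was backed by few genes in the direct test. Camera called the periportal (adjusted p = 2.83e-06), acute phase (3.28e-06), gluconeogenesis (4.96e-06), unfolded protein (0.00281) and female-biased (0.0216) lists lower for the interaction, and the macrophage (0.00281) and p53 (0.0376) lists higher. None of these calls held, with adjusted p = 0.787 with an estimated correlation for the p53 list and 0.758 for each of the others. Without WT_CT16 library 8 the female-biased call ended (0.0995) and NRF2 targets were called lower (0.0484). No estimated correlation was run without library 8, and with all libraries it gave adjusted p = 0.758 for both lists.

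In some lists the median, the mean and the direction of camera differed in sign, and camera called none of these. They were transporters and interferon genes for the times in WT. For the times in libraries labelled CryDKO they were female-biased, acute phase, interferon and unfolded protein genes. By genotype at CT8 they were transporters, xenobiotic and cholesterol genes. At CT16 they were transporters, cholesterol, bile acid, gluconeogenesis, acute phase, pericentral and endothelial genes. For the interaction they were nucleotide excision repair, xenobiotic, cholesterol, heat shock, proliferation and endothelial genes.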

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

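The tests on WT_CT16 library 8, GC content, a batch, sharing between Mup genes and other splits were chosen after the result was seen. A value far from the other 3 of its group appeared in 47 of 556 groups of 4 examined, 8.45%, where chance flags about 1 in 20 if values are normally distributed. CPM were not put on a log scale here, and skewed values can be flagged more often. The excess over 1 in 20 is thus no evidence of deviating libraries.

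WT_CT16 library 8 stood apart from its group. Its scaling factor was 1.20, against 0.921 to 0.955 in the other libraries of the group, its rank correlation was 0.992 with the WT_CT8 libraries and 0.983 with its own group, and among genes it was far from the others in Cyp7a1 (834 CPM, highest), Gsr (43.4 CPM, lowest), Hdc (12.9 CPM, highest), Hspa5 (215 CPM, lowest), Mup-ps16 (29.0 CPM, highest), Srp54a (1.74 CPM, lowest) and Xaf1 (12.9 CPM, highest). Cyp2b13 (0.0697 CPM, highest) and Nat8f7 (0.0349 CPM, highest) were also far in it, but on 2 reads and 1 read where the group had no others, under a floor of 3 reads, so they say nothing about the library. Libraries labelled CryDKO were also mixed between the times: CryDKO_CT8 libraries 15 and 16 correlated more with CryDKO_CT16 (0.991 and 0.988) than with their own group (0.987 and 0.986), and CryDKO_CT16 libraries 11 and 12 more with CryDKO_CT8 (0.991 and 0.990) than with theirs (0.987 and 0.987). A mislabelled WT_CT8 library was argued against by clock genes, but not excluded. Of 8 that separated the times in the other libraries, library 8 lay nearer to WT_CT16 in 6 (75%, 95% CI 34.9 to 96.8, exact), all 6 beyond the WT_CT8 range. Among other genes it did so in 990 of 5917 (Fisher's exact test, two-sided, p = 0.000458). The interval is wide, and the test takes genes as independent, which clock genes are not. Per2, among the 6, lay about midway (0.516, with 0 for WT_CT8 and 1 for WT_CT16). The pattern was not limited to noncoding or low-abundance RNA. Of 1871 abundant protein-coding genes that separated the times, only 12.3% (95% CI 10.9 to 13.9, exact, genes taken as independent) lay nearer to WT_CT16. This cannot decide whether RNA composition was the cause, since the groups that these genes separate differ in it too. Long noncoding RNA made up 0.691% to 0.869% of reads in WT_CT8, 0.320% to 0.428% in WT_CT16 libraries 5 to 7 and 0.752% in library 8. A difference between animals, such as a weaker response in that liver, was not tested and remains open.

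Genotype differences followed the GC content of transcripts, with a median log2 change at CT8 from -0.34 in 2687 genes of lowest GC to 0.28 in 2687 genes of highest GC, and at CT16 from -0.29 to 0.30. A GC bias as the whole source of the changes was argued against, since many genes kept call and sign after the trend was removed. They were 72.4% (95% CI 71.3 to 73.6, exact) of the 5649 at CT8 and 48.1% (46.2 to 50.01) of the 2629 at CT16, with genes taken as independent. Only the 92.8% of tested genes with a known GC content were corrected, so kept calls of the rest are no evidence. A GC bias stays open for these uncorrected genes and for the 1557 and 1365 genes that were not kept. The median size of log2 change of the genes not kept went from 0.56 to 0.33 at CT8 and from 0.61 to 0.38 at CT16. Their median SE was 0.17 before and after at both times, so calls ended as changes shrank. A library batch that follows genotype may be a source too: the lowest library labelled CryDKO lay 0.276 above the highest WT library in its rank correlation with GC, and no label gives a batch, so batch and genotype cannot be told apart. A GC-linked change in the transcripts themselves was not tested.

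In the libraries labelled CryDKO 7 of 14 female-biased genes rose and 1 fell at CT8, and 4 rose and 1 fell at CT16. Of 18 male-biased genes 5 fell at CT8 and 3 at CT16, and 0 rose. No call of either list held with an estimated correlation (adjusted p = 0.797 at CT8 and 0.994 at CT16). Female livers among these libraries were argued against by Y-linked reads, at least 51.4% of the WT mean in each library, close to the bound of 50% set beforehand, and by Xist, at most 0.174 CPM. Sharing of reads between Mup genes as the whole source of their falls was argued against at CT8, where the highest sum over Mup genes in a library labelled CryDKO, 4679 CPM, lay below the lowest in WT, 10601 CPM. At CT16 it stays open, because CryDKO_CT16 library 13, at 10305 CPM, lay above the lowest WT library, at 7816 CPM, while the other 3 lay below it. Sharing concerns the Mup genes alone and not Nudt7. A change in hormonal control of the liver in these animals may also be open beside these values, and it was not tested.

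The interaction of genotype and time differed from 0 in Cyp2j9 (2.05), Gm43549 (3.38), LOC118568335 (3.38), Ppib (-1.72), Sult5a1 (2.98) and Tnfaip3 (-2.09), on the log2 scale by edgeR's quasi-likelihood test. Among lists it did so by camera for p53 targets (adjusted p = 0.0376), female-biased genes (0.0216), gluconeogenesis and amino acid catabolism (4.96e-06), acute phase response (3.28e-06), unfolded protein response (0.00281), periportal genes (2.83e-06) and macrophage markers (0.00281), with adjusted p = 0.787 with an estimated correlation for the p53 list and 0.758 for the others.

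Other splits of the same libraries were counted. For the times in WT, 2 of 35 splits gave as many genes as the real 367, so chance cannot be excluded, and the highest other, with 1045, set libraries 1, 2, 4 and 8 against 3, 5, 6 and 7, which points to a structure of the samples. For the times in the libraries labelled CryDKO all 35 of 35 did, the real count being 0 and the highest other 27. For genotype 1 of 35 did at CT8 (5649, highest other 0) and 1 of 35 at CT16 (2629, highest other 35). That share, 0.0286, is the smallest that 35 splits can give. Every other split mixed the genotypes within a group, which widens the fitted spread. The real split gave the most genes at both times, but the splits do not exclude chance or a batch that follows genotype. For the interaction 2 of 100 drawn splits did (6, highest other 7), a share under 5%. Most of the drawn splits mixed the times within a group, which can widen the fitted spread, so this share does not exclude chance either.

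Single libraries far from the rest of their group were as follows. WT_CT8 library 1 stood apart in Lingo4 (4.19 CPM, highest), Mup-ps16 (48.2 CPM, highest) and Tnfaip3 (1.80 CPM, lowest). WT_CT16 library 5 did in Bhlhe41 (8.62 CPM, highest), library 6 in Abcc4 (4.89 CPM, highest), Cyp17a1 (42.7 CPM, highest), Lepr (4.68 CPM, highest), Lpl (53.4 CPM, highest), Lrtm2 (7.59 CPM, highest) and Pdk4 (3.56 CPM, highest), and library 7 in Saa3 (25.8 CPM, highest). CryDKO_CT8 library 9 did in Aqp4 (5.10 CPM, highest), Cd14 (21.0 CPM, highest), Gsr (118 CPM, highest) and Tdg-ps2 (18.04 CPM, highest), library 10 in its albumin share of reads (9.63%) and in Clec2h (2.34 CPM, highest), Cyp2a5 (494 CPM, highest), Ddit4l (3.55 CPM, lowest) and Tcim (42.01 CPM, highest), library 15 in the lowest number of genes with at least 5 reads (14026) and in Mup11 (15.7 CPM, highest), and library 16 in its share of long noncoding RNA (0.716%) and in Mup-ps16 (0.595 CPM, highest) and Uvssa (16.3 CPM, highest). CryDKO_CT16 library 11 did in Hspa5 (299 CPM, lowest) and Mgst1 (1791 CPM, lowest), library 12 in Lbp (310.0 CPM, highest), library 13 in principal component 1 (-30.8) and in C1qa (26.9 CPM, highest), Hdc (14.6 CPM, highest), Hsd3b5 (22.6 CPM, highest) and Pnldc1 (1.37 CPM, highest), and library 14 in Ctsl (1407 CPM, highest), Gpt (817 CPM, highest), Pcx (1039 CPM, highest) and Tnfaip3 (3.23 CPM, highest).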

How the results depend on the processing

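The GC correction and the list tests without WT_CT16 library 8 were chosen after the result was seen. No named gene past the threshold changed sign in any alternative run, and no list called by camera was called the other way in the directional list tests run. The balance of rises and falls did turn: for the times in WT it went from 179 and 188 to 441 and 222 without a low count filter and to 18 and 354 with scaling by library size alone. That scaling also turned the balance of several lists by genotype, such as the p53 list at CT8 (6 and 3 to 2 and 6). The count at CT8 stayed within 1.5 times of 5649 in all alternatives but the 2-fold threshold (2279), and that at CT16 in all but the 2-fold threshold (890) and the GC correction (1493). For the times in WT the 367 genes became 663 without a low count filter, 1570 with DESeq2, 955 with limma voom, 5237 with quality weights, 712 with only the 2 groups, 118 with limma trend on the deposited normalized values and 106 with a 2-fold threshold. For the times in CryDKO the 0 genes of edgeR's quasi-likelihood test (938 at an unadjusted p under 0.05) became 2 without a filter, 13 with DESeq2 and 1 with limma trend, and stayed 0 with limma voom. For the interaction the 6 genes became 0 with scaling by library size alone, 30 without a filter, 1 with a mean of at least 50 reads, 133 with DESeq2, 1 with limma voom, 940 with quality weights and 10 with limma trend. For each of these the cause was not tested, except that a 2-fold threshold selects among the same genes. Leaving out 1 library gave 0 to 3580 genes for the times in WT, 0 to 3 in CryDKO, 4274 to 6112 at CT8, 1821 to 2742 at CT16 and 0 to 568 for the interaction. Named calls held in every alternative for 0 of 36 genes for the times in WT and 0 of 4 for the interaction. By genotype 79 of 113 held at CT8 and 52 of 91 at CT16. Without some library 21 of these calls were lost at CT8 and 36 at CT16, and with the GC correction 12 and 29. Counted over every gene and setting, among named genes 6058 results kept their side of the threshold, 757 fell short of it and 17 passed it newly, and among list tests by camera 508, 44 and 8 did. With limma's fry in place of camera, which does not compare a list with other genes, 107, 33 and 0 did in its directional test and 88, 23 and 29 in its mixed test, which has no direction. The camera calls that the directional test kept were all by genotype at CT8. They were the female-biased, periportal, unfolded protein, NRF2 and glutathione lists, each with fry adjusted p = 0.0449, close to the threshold. With scaling by library size alone the median log2 change went from -0.04 to -0.29 for the times in WT, from 0.00 to -0.06 in CryDKO, from -0.02 to -0.36 at CT8, from -0.01 to -0.16 at CT16 and from 0.01 to 0.20 in the interaction. No paired analysis was possible because the columns carry a running number over the series and no replicate numbers, so the planned replicate block was not run, and the interaction has no fit of 2 groups. For the times in WT, the only comparison in which recovery of simulated changes was counted, 14% of 1.5-fold changes were called at this depth. Changes of that size were thus mostly not detectable there. Apart from the changes set in, the simulation drew all libraries from a common mean per gene. It held no library that deviates like WT_CT16 library 8.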

Other observations

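The tests around Cry1 and Cry2 in this part were chosen after the result was seen, and Alb, Apoa4, C4a, Malat1 and Tdg lie outside the rule for named genes and were chosen after their values were seen. Meg3 met the rule for the times in WT only. Its values by genotype were also chosen after they were seen, and were not followed in the alternatives. Adjusted p values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

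Albumin reads made up 4.27% of reads in WT at CT8, 4.89% in WT at CT16, 7.78% in libraries labelled CryDKO at CT8 and 7.89% in those at CT16. Apoa4, an apolipoprotein gene, stood at 159 ± 61.7 CPM in WT at CT8 and 5231 ± 5984 CPM in libraries labelled CryDKO at CT8 (log2 change 5.04 ± 0.81, adjusted p = 0.000547), with a wide spread. At CT16 Apoa4 stood at 405 ± 308 CPM in WT and 1031 ± 343 CPM in libraries labelled CryDKO, which did not pass. The complement gene C4a fell at CT8 from 84.3 ± 38.5 to 5.23 ± 3.53 CPM (log2 change -4.03 ± 0.75). It has a close paralog, so its value alone is uncertain.

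Long noncoding RNA made up 0.776% of reads in WT at CT8, 0.480% in WT at CT16, 0.421% in libraries labelled CryDKO at CT8 and 0.320% in those at CT16. The mean of CryDKO_CT8 was carried by library 16, at 0.716%, where the other 3 lay at 0.316% to 0.336%, and WT_CT16 library 8 had 0.752%, where the other 3 lay at 0.320% to 0.428%. Malat1 stood at 656 ± 80.5, 283 ± 133, 295 ± 93.0 and 253 ± 69.9 CPM in these groups. Meg3, an imprinted gene, fell by genotype with a log2 change of -3.32 ± 0.40 at CT8 (adjusted p = 1.93e-05) and -2.46 ± 0.43 at CT16 (adjusted p = 0.000862).

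A hypothesis was that a chromosome segment of another strain, carried along with each targeted gene, could account for differences that hold at both times, although the labels give both genotypes the same strain. Genes changed at least 2-fold at both times made up 3 of 100 neighbours of Cry1 (odds ratio 0.934, 95% CI 0.189 to 2.83, Fisher's exact test) and 6 of 100 neighbours of Cry2 (odds ratio 1.94, 95% CI 0.691 to 4.42, two-sided p = 0.140, adjusted p = 0.559). As the whole source, through the genes such segments carry, it was argued against: of 431 genes changed at least 2-fold at both times and placed in the annotation, 375 lay on other chromosomes than Cry1 and Cry2, and 12.99% (95% CI 9.97 to 16.5, exact) on theirs. Of the other placed genes 12.8% lay on these 2 chromosomes. That result was nearly certain beforehand, since 2 segments could hardly hold most of 431 genes. The intervals of the odds ratios leave the hypothesis open for these neighbours alone. Tdg, a neighbour of Cry1, fell at CT8 (-0.74 ± 0.20) and CT16 (-0.82 ± 0.20) on the log2 scale, while its pseudogene Tdg-ps2 had 7 and 4 reads over the WT groups and 1000 and 966 over the groups labelled CryDKO at CT8 and CT16.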
